A study of Mus musculus with 6 samples.

How the data were processed

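Expression was measured by RNA sequencing in 6 samples, a serrated polyp and the surrounding normal distal cecum of each of 3 HBUS mice. Per the labels' protocols, tissue was kept in RNAlater, RNA was isolated after bead homogenization, treated with the MICROBEnrich kit, which removes mammalian RNA to enrich bacterial RNA, and then with a Meta-Bacteria RiboZero kit for rRNA, before paired-end Illumina libraries were made with an NEBNext mRNA kit and PCR. The labels read as if the mouse counts come from this treated RNA, in which case they cover what was left after mouse RNA was removed, but this is not certain. The mitochondrial rRNAs took 46.3% to 75.3% of the counts. The labels do not say whether strand was kept, so reads of a gene and of an overlapping or antisense gene may not have been told apart.

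The deposited values are raw counts per gene, 1 table per sample, with whole numbers for 37991 Ensembl gene identifiers, and the authors applied no normalization to these counts per the file headers and values. TopHat2 2.0.7, Bowtie 0.12.9 and HTSeq 0.5.3p9 are named in the submitters' processing notes, and their settings, the genome build and the annotation release are not given in the sources used here. Gene names came from a table of GENCODE M21, which named 32919 identifiers; the other 5072 kept their identifier, 237 of them were tested and 2 changed. No coordinates are given because the build is unknown. Gene lengths and GC content for a check came from the same annotation. Fragments are not marked with molecular identifiers, so detection floors of 3 counts cover counting error only. These floors (0.225 to 0.452 CPM) were taken over raw library totals, while other CPM values were normalized for library composition. Normalized, the floor is higher in surrounding tissue of mouse 1199 (factor 0.593) and lower in the polyp of mouse 1192 (factor 1.43).

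Genes were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by the quasi-likelihood test with robust spread estimates, TMM normalization and a filter on low counts (filterByExpr with its minimum count of 10), which kept 10960 genes. The mouse was a block in the model, since the series is described as paired and the mouse number in each title says which samples share an animal; p-values were adjusted by Benjamini-Hochberg and called under 0.05. The test was two-sided, with 2 residual degrees of freedom per gene before 6.63 prior degrees of freedom were added, and the common biological coefficient of variation was 34.3%. TMM factors ran from 0.593 (surrounding tissue, mouse 1199) to 1.43 (polyp, mouse 1192). As a check on the pairing, deviations from the tissue means were correlated over genes. Samples of the same mouse (1119, 1192 and 1199) gave 0.0719, 0.127 and 0.159. Samples of different mice gave -0.1199 to -0.00294. Deviations from a tissue mean cancel out over its samples, so positive values within mice push those between mice below 0. The negative values are therefore no separate evidence for the pairing. Replicates of a tissue differed by more than sampling noise (chi-square per degree of freedom 9.89 to 31.5), so none was treated as a copy of another.

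The 44 gene lists for pathways, cell types and RNA quality were fixed before the data were examined, and those with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over 38 lists. Genes named were the 10 with the largest rise and the 10 with the largest fall among called genes with the same sign in all 3 mice and a mean log2 CPM of at least 3, leaving out gene models without a proper name, pseudogenes and antigen receptor segments; up to 4 genes with the smallest p in each list described; and 12 genes chosen beforehand (Hbegf, Egfr, Areg, Ereg, Muc5ac, Muc2, Lgr5, Mki67, Il1b, S100a8, Mmp10 and Cdkn2a). Of the genes this rule names, 2 are not reported here. The procedure was tested on simulated counts for the polyp comparison, 5 sets of 10960 genes with 200 changed in each: it recovered 26.6% of 500 genes changed 2-fold and 63.0% of 500 changed 4-fold, and 10.2% of 499 calls were genes left unchanged, above the nominal 5%. A raised list of 20 genes was called in 5 of 5 sets and 2 of 190 unchanged lists were. Simulated genes varied independently of each other, so these list results cannot gauge camera on lists whose genes move together.

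Alternatives set beforehand were no block for the mouse, RLE and upper-quartile normalization, leaving out genes above 1% of a library, no filter on low counts, a mean of at least 5 CPM, spread estimated without robustness, leaving out each mouse, DESeq2 1.42.0, limma-voom, a test against a log2 fold change of 1, camera with an estimated correlation, and fry. Removal of each library's trend with transcript length and GC content was chosen after seeing the data. A list of 25 general epithelial genes was written for a check of tissue composition, also after seeing the data. Tables and figures were made with Python 3.11.15.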

Results

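RNA was sequenced from the cecum of 3 HBUS mice at 60 weeks of age, with 1 serrated polyp sample and 1 sample of surrounding normal distal cecum from each animal, so 6 libraries formed 3 pairs. HBUS mice carry transgenes for the growth factor HB-EGF and the viral chemokine receptor US28 in the intestinal epithelium and develop serrated polyps, lesions with a saw-toothed crypt outline, in the cecum. The values were raw counts per gene, and the comparison asked which genes differ between a polyp and the tissue around it in the same animal. Total counts ran from 6632645 (polyp, mouse 1199) to 13350119 (surrounding tissue, mouse 1192). The 2 mitochondrial rRNA genes took between 46.3% (polyp, mouse 1192) and 75.3% (surrounding tissue, mouse 1199) of them, which left 1852065 to 5096066 counts for all other genes. At an equal thinned depth of 1852065 such counts, the polyp library of mouse 1192 had counts for 12326 genes and the other libraries for 14295 to 16086. Levels are given in CPM (counts scaled to a common library size after normalization for library composition) as mean ± SD (n = 3 mice). Log2 fold changes are polyp over surrounding tissue (n = 3 pairs), ± standard error. This error was derived from the edgeR test statistic, whose spread estimate borrows from other genes, and not from the spread of the pairs alone.

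**Figure D1:**
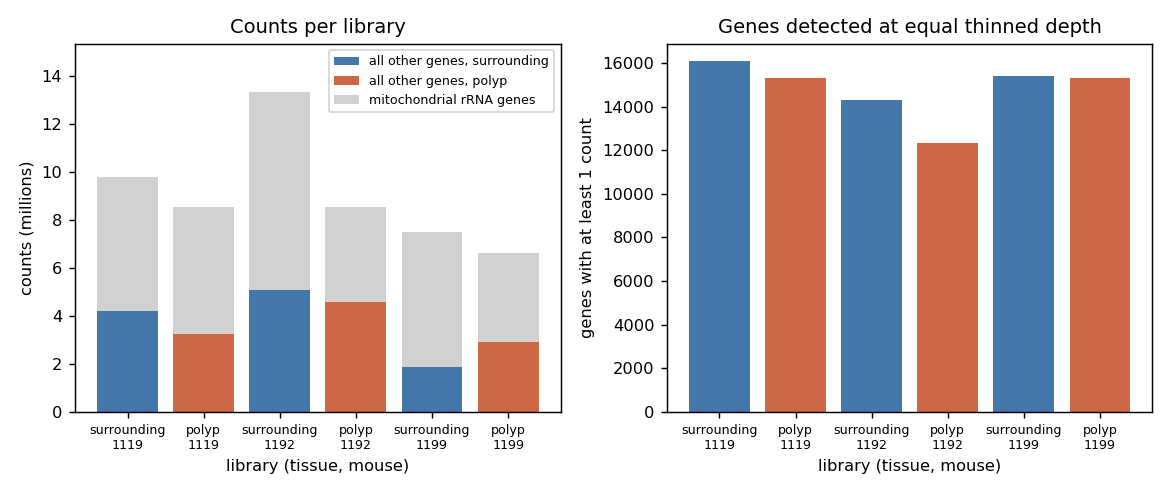
Left, counts per library, split into the 2 mitochondrial rRNA genes (grey) and all other genes (blue, surrounding tissue; orange, polyp); right, number of genes with at least 1 count after each library was thinned to the same number of counts outside the mitochondrial rRNA genes. The polyp library of mouse 1192 kept the fewest genes, 12326, and the surrounding library of mouse 1199 held 1852065 counts outside the mitochondrial rRNA genes.

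In polyps, 12 of 22 fibroblast and collagen genes and 9 of 13 basement membrane and laminin genes rose, and 7 of 24 absorptive colonocyte genes fell, against the surrounding cecum of the same mouse. These lists passed a test against other genes (camera) at its preset correlation, with adjusted p = 0.205, 0.205 and 0.205 with an estimated correlation. The estimated correlation is tested on 2 residual degrees of freedom, which leaves it little power. Col3a1 (ENSMUSG00000026043), a fibrillar collagen, rose 4.24-fold, from 43.8 ± 22.4 to 180.3 ± 73.6 CPM (adjusted p = 0.00173). Slc26a3 (ENSMUSG00000001225), the chloride and bicarbonate exchanger of the colonocyte surface, was 4.72-fold lower, from 478 ± 103 to 103 ± 31.02 CPM (adjusted p = 0.00523). Of 10960 genes tested, 303 changed, 189 higher and 114 lower in polyps (edgeR quasi-likelihood test with the mouse as a block, Benjamini-Hochberg adjusted p under 0.05). All 303 moved in the same direction in each of the 3 mice, which a paired test on these same mice favours when it selects genes. Without mouse 1119, 1192 or 1199 the counts were 83, 281 and 100, with 71, 198 and 84 of the 303 genes kept. Ignoring the pairing gave 87 genes. In simulated libraries of this size, with 200 of 10960 genes changed, 10.2% of the genes called had not been changed. Simulated genes varied independently of each other, so this is not the share of false calls among the 303.

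Among called genes of at least moderate abundance, the largest rise was that of Pappa (ENSMUSG00000028370), a metalloprotease that cleaves insulin-like growth factor binding proteins, which went from 2.25 ± 2.42 to 15.6 ± 9.18 CPM (log2 fold change 3.27 ± 0.64, adjusted p = 0.0379). Next came Arg1, the cytosolic arginase (log2 fold change 3.08 ± 0.50), and Tnfrsf11b, the decoy receptor osteoprotegerin (3.07). The chemokine gene Cxcl14 rose 8.24-fold and the sphingosine-1-phosphate transporter gene Spns2 7.98-fold. Col5a2, another fibrillar collagen, had a log2 fold change of 2.99 and the serine protease gene Prss22 2.97. For the acyl-CoA synthetase gene Acsbg1 it was 2.97, for Trim29 2.76 and for the TNF receptor family gene Tnfrsf23 2.68. The largest fall was that of Nxpe4 (ENSMUSG00000044229), from 32.5 ± 10.3 to 1.77 ± 1.75 CPM (log2 fold change -4.25 ± 0.57, adjusted p = 0.0153). Car4, a membrane-bound carbonic anhydrase, followed with 9.17-fold less transcript (log2 fold change -3.20 ± 0.40). Then came the thyroid hormone deiodinase gene Dio1 (-2.51), the sulfotransferase gene Gal3st2c (-2.34) and the smooth muscle gene Tagln (-2.28). Ido1, the tryptophan-degrading enzyme induced by interferon, fell by 2.26 on the log2 scale, and Sectm1b by 2.04. The pyruvate dehydrogenase kinase gene Pdk4 fell by 2.03 and the interferon-inducible GTPase gene Ifi47 by 1.98. Tested against a log2 fold change of 1 instead of 0, 3 genes passed, Col3a1, Gal3st2c and Sectm1b. Gal3st2c, Sectm1b and Tnfrsf23 belong to groups of related neighbouring genes, and reads shared between such copies could not be followed in these counts.

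**Figure D2:**
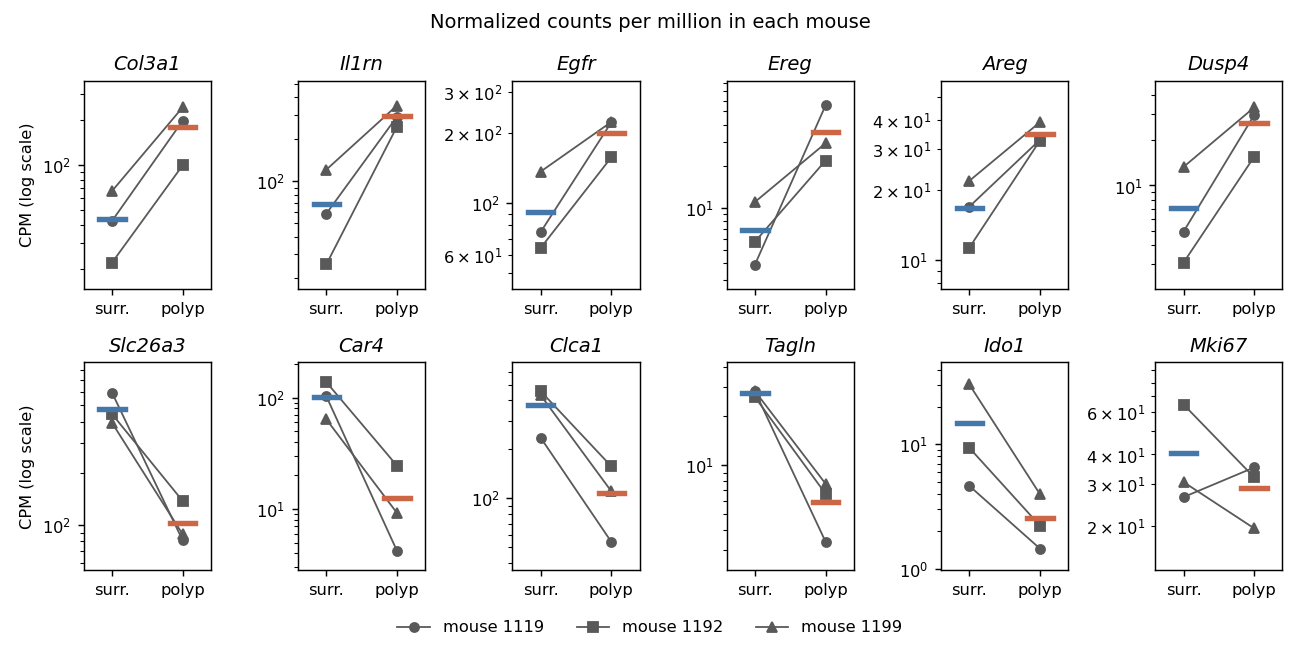
Normalized CPM (log scale, a separate scale for each gene) of 12 genes in surrounding tissue (surr.) and polyp; each line joins the 2 samples of a mouse and the coloured bars are means of 3 mice. Lines of the first 11 genes run in 1 direction in all 3 mice, whereas Mki67 was higher in the polyp of mouse 1119 and lower in those of the other 2 mice.

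Transcripts of the epidermal growth factor receptor and of 2 of its ligands rose in polyps. Egfr (ENSMUSG00000020122) went from 91.8 ± 39.01 to 201 ± 37.8 CPM (2.28-fold, adjusted p = 0.0153). The ligand gene Ereg went from 6.87 ± 3.72 to 35.6 ± 17.5 CPM (5.197-fold, adjusted p = 0.0331) and the ligand gene Areg from 16.7 ± 5.28 to 34.7 ± 3.66 CPM (2.15-fold, adjusted p = 0.0334). Hbegf itself, the mouse gene of the growth factor used as a transgene in this strain, was measured at 27.9 ± 13.95 CPM in surrounding tissue and 38.5 ± 7.38 in polyps and did not pass the test (log2 fold change 0.56 ± 0.23, adjusted p = 0.306). Whether reads of the transgene count toward it is not known from the sources used here. Nrg1, a ligand of other receptors of the family, had 1.56 ± 2.01 and 8.24 ± 2.11 CPM (adjusted p = 0.1397). In the whole EGFR family and ligand list, 3 of 11 tested genes rose and 0 fell (4 and 0 adjusted over the list alone), with a median log2 fold change of 0.56 (0.31 without mouse 1192 and 0.91 without mouse 1199). For EGFR family and ligands, camera gave adjusted p = 1.57e-05, and adjusted p = 0.351 with an estimated correlation. Of the ERK pathway list, feedback regulators and targets of the kinase cascade downstream of these receptors, 4 of 14 tested genes rose and 0 fell (6 and 0 adjusted over the list alone). For ERK pathway feedback and target genes, camera gave adjusted p = 1.22e-07, and adjusted p = 0.205 with an estimated correlation. The phosphatase gene Dusp4 had 4.22 times its surrounding level, and Phlda1 4.11 times. Dusp5 had 3.96 times and the ephrin receptor gene Epha2 2.78 times (adjusted p between 0.0153 and 0.0221). Of immediate early genes, which many stimuli and tissue handling itself induce, 3 of 11 tested genes rose and 0 fell (7 and 0 adjusted over the list alone). For immediate early genes, camera gave adjusted p = 1.42e-08, and adjusted p = 0.205 with an estimated correlation. Dusp1 rose by 1.36 ± 0.20, Fos by 0.95 ± 0.15 and Egr1 by 1.70 ± 0.36 on the log2 scale, while Atf3 missed the threshold at 1.00 ± 0.22 (adjusted p = 0.0559). EGFR family genes that passed numbered 0, 1 and 1 without mouse 1119, 1192 or 1199 and 1 without the pairing. In the same order ERK genes that passed numbered 1, 4, 3 and 1, and immediate early genes 0, 3, 0 and 1.

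Among genes of regenerating and fetal-like epithelium, 6 of 14 tested genes rose and 0 fell (12 and 0 adjusted over the list alone). For regenerative and fetal-like epithelium genes, camera gave adjusted p = 5.12e-21, and adjusted p = 0.205 with an estimated correlation. All 14 log2 fold changes of this list were positive, with a median of 2.12. The samples were whole tissue, and which cell types carried this rise was not measured. Il1rn, the interleukin-1 receptor antagonist, rose 5.18-fold from 68.1 ± 48.5 to 295 ± 51.6 CPM (adjusted p = 0.0153). The keratin gene Krt7 rose 3.73-fold from 43.7 ± 33.5 to 136 ± 29.6 CPM (adjusted p = 0.0153). Anxa3, an annexin, had a log2 fold change of 1.70 ± 0.19 (adjusted p = 0.00827) and Sprr1a, a cornified envelope gene, 1.62 ± 0.29 (adjusted p = 0.0283). Members that passed numbered 4, 3 and 9 without mouse 1119, 1192 or 1199 and 0 without the pairing. In the tight junction list, 1 of 15 tested genes rose and 0 fell (2 and 0 adjusted over the list alone). For tight junction and claudin genes, camera gave adjusted p = 0.00659, and adjusted p = 0.306 with an estimated correlation. The member that passed, the claudin gene Cldn4, went from 121 ± 59.5 to 294 ± 79.7 CPM (adjusted p = 0.0138). It did not pass without the pairing, and the list lost its call without mouse 1192 (adjusted p = 0.198). Of the glycolysis and hypoxia list, 2 of 21 tested genes rose and 0 fell (5 and 0 adjusted over the list alone). For glycolysis and hypoxia genes, camera gave adjusted p = 1.41e-05, and adjusted p = 0.205 with an estimated correlation. The members that rose were the lactate transporter gene Slc16a3 (log2 fold change 1.42 ± 0.19) and Egln3, a HIF prolyl hydroxylase gene (log2 fold change 0.70 ± 0.15), and 1 member passed with each mouse left out in turn and without the pairing. The squamous and enteric neuron lists had 2 tested genes each and were not tested as lists. Among them Sfn (stratifin) rose by 0.81 ± 0.17 and Ret, a receptor kinase gene, by 2.60 ± 0.45 on the log2 scale. Sfn did not pass with any 1 mouse left out, without the pairing, with upper-quartile normalization, without robust spread estimates or with length and GC trends removed, and Ret did not pass without mouse 1119 or 1199.

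In the fibroblast and collagen list 12 of 22 tested genes rose and 0 fell (17 and 0 adjusted over the list alone). For fibroblast and collagen genes, camera gave adjusted p = 2.02e-38, and adjusted p = 0.205 with an estimated correlation. All 22 log2 fold changes were positive, with a median of 1.60. Beside Col3a1, Col1a2 rose 4.23-fold from 16.2 ± 5.36 to 71.2 ± 31.2 CPM (adjusted p = 0.00304). Col6a3 rose 6.03-fold (adjusted p = 0.00523) and the fibronectin gene Fn1 3.37-fold (adjusted p = 0.00523). In the basement membrane and laminin list 9 of 13 tested genes rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 1.62. For basement membrane and laminin genes, camera gave adjusted p = 6.54e-22, and adjusted p = 0.205 with an estimated correlation. Col4a2 went from 8.39 ± 3.52 to 32.5 ± 10.1 CPM (adjusted p = 0.00777). The log2 fold changes of the nidogen gene Nid1, the laminin gene Lamb1 and Col4a1 were 1.86 ± 0.22, 1.61 ± 0.24 and 1.62 ± 0.24. Of the matrix metalloproteinase and protease list 2 of 12 tested genes rose and 0 fell (7 and 0 adjusted over the list alone), at a median of 2.09. For matrix metalloproteinase and protease genes, camera gave adjusted p = 2.87e-09, and adjusted p = 0.205 with an estimated correlation. Mmp2 had 5.095 times its surrounding level (adjusted p = 0.0232) and the urokinase gene Plau 3.53 times (adjusted p = 0.0234). Plat and Mmp12 missed the threshold (adjusted p = 0.0603 and 0.0805). So did Mmp10, at 2.06 ± 2.25 CPM in surrounding tissue and 22.9 ± 12.3 in polyps (adjusted p = 0.0922). Fibroblast and collagen genes that passed numbered 8, 15 and 8 without mouse 1119, 1192 or 1199 and 7 without the pairing. In that order, basement membrane genes that passed numbered 2, 8, 2 and 4, and metalloproteinase and protease genes 0, 3, 3 and 0.

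In the TGF-beta and BMP list, 2 of 15 tested genes rose and 0 fell (6 and 0 adjusted over the list alone). For TGF-beta and BMP pathway genes, camera gave adjusted p = 6.05e-04, and adjusted p = 0.205 with an estimated correlation. The genes that rose were the receptor gene Tgfbr2 (log2 fold change 1.05 ± 0.17) and Tgfbi, a secreted matrix protein gene induced by TGF-beta (log2 fold change 1.62 ± 0.30). Bmp2 and Bmp4 did not pass (adjusted p = 0.0751 and 0.184). This was the list that passed fry, a directional set test that does not compare a list with other genes (adjusted p = 0.0148). TGF-beta and BMP genes that passed numbered 0, 1 and 0 without mouse 1119, 1192 or 1199 and 1 without the pairing. All 12 tested endothelial and lymphatic genes had a positive log2 fold change, with a median of 1.05, although 0 passed singly, also 0 adjusted over the list alone. For endothelial and lymphatic genes, camera gave adjusted p = 4.55e-04, and adjusted p = 0.205 with an estimated correlation. The 4 genes with the smallest p, Vwf, Vegfa, Eng and Cdh5, had log2 fold changes of 1.08 ± 0.37, 0.58 ± 0.20, 1.50 ± 0.54 and 1.99 ± 0.74. Of 16 tested smooth muscle genes, 15 had a negative log2 fold change, with a median of -1.45, and 2 fell (7 adjusted over the list alone). For smooth muscle genes, camera gave adjusted p = 1.19e-08, and adjusted p = 0.205 with an estimated correlation. Tagln went from 27.6 ± 1.29 to 5.91 ± 2.24 CPM (adjusted p = 0.0116) and Synpo2 from 21.9 ± 1.21 to 7.56 ± 2.81 CPM (adjusted p = 0.0291). Pgm5 and Actg2 were at -2.82 and -3.89 with adjusted p = 0.0517 and 0.0582. The median smooth muscle difference was -2.14 in mouse 1119, -0.69 in mouse 1192 and -1.35 in mouse 1199. Smooth muscle genes that passed numbered 2, 5 and 1 without mouse 1119, 1192 or 1199 and 1 without the pairing.

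In the list of absorptive colonocytes, the differentiated surface cells, 0 of 24 tested genes rose and 7 fell (0 and 11 adjusted over the list alone), with a median log2 fold change of -0.65. For absorptive colonocyte genes, camera gave adjusted p = 2.19e-13, and adjusted p = 0.205 with an estimated correlation. Beside Slc26a3 and Car4, the magnesium channel gene Trpm6 went from 42.4 ± 8.301 to 11.8 ± 4.71 CPM (adjusted p = 0.00827) and the water channel gene Aqp8 from 354 ± 57.9 to 135 ± 19.8 CPM (adjusted p = 0.0116). Of the fatty acid oxidation and PPAR target list, 0 of 17 tested genes rose and 3 fell (0 and 4 adjusted over the list alone). For fatty acid oxidation and PPAR target genes, camera gave adjusted p = 9.95e-06, and adjusted p = 0.205 with an estimated correlation. Besides Pdk4, the genes that fell were the fatty acid binding protein gene Fabp2 (log2 fold change -1.21 ± 0.24) and the carnitine palmitoyltransferase gene Cpt1a (log2 fold change -0.73 ± 0.15). Hadhb was at -0.91 ± 0.22 without passing. Of the xenobiotic and steroid metabolism list, 0 of 21 tested genes rose and 5 fell (3 and 12 adjusted over the list alone). For xenobiotic and steroid metabolism genes, camera gave adjusted p = 2.88e-07, and adjusted p = 0.311 with an estimated correlation. Among those that fell were the steroid dehydrogenase gene Hsd3b3 (log2 fold change -1.25 ± 0.16) and the sulfotransferase gene Sult1a1 (log2 fold change -1.93 ± 0.32). The cytochrome P450 gene Cyp3a13 (log2 fold change -0.75 ± 0.13) and the carboxylesterase gene Ces2c (log2 fold change -0.91 ± 0.18) fell too. The ion and water transport list had 1 called member higher and 2 lower (1 and 4 adjusted over the list alone) and did not pass as a list (camera adjusted p = 0.117). The kinase gene Sgk1 and the mineralocorticoid receptor gene Nr3c2 fell by 0.98 and 0.73, and the chloride channel gene Ano1 rose by 1.49 on the log2 scale. None of these 3 passed without mouse 1119, without mouse 1199 or without the pairing, and 1 of the list passed without mouse 1192. Colonocyte genes that passed numbered 5, 9 and 5 without mouse 1119, 1192 or 1199 and 3 without the pairing. In that order fatty acid genes numbered 0, 2, 0 and 0, and xenobiotic genes 1, 9, 0 and 0.

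Some secreted products of goblet cells, the mucus-producing cells, fell, and the main mucin did not pass. In the goblet cell and mucus list, 0 of 19 tested genes rose and 3 fell (0 and 5 adjusted over the list alone). For goblet cell and mucus genes, camera gave adjusted p = 1.57e-05, and adjusted p = 0.351 with an estimated correlation. Clca1, a secreted mucus protein gene, went from 375 ± 121 to 108 ± 51.8 CPM (adjusted p = 0.00304). The lectin gene Zg16 went from 229 ± 26.2 to 97.4 ± 32.1 CPM (adjusted p = 0.0155) and the mucus protein gene Fcgbp from 1308 ± 174 to 720.2 ± 383 CPM (adjusted p = 0.0473). Muc2, the gel-forming mucin of the large intestine, was at 1063 ± 144 and 895 ± 211 CPM (log2 fold change -0.27 ± 0.14, adjusted p = 0.456). Atoh1, the secretory lineage transcription factor gene, was at a log2 fold change of -1.37 ± 0.32 (adjusted p = 0.0711). Goblet cell and mucus genes that passed numbered 2, 4 and 1 without mouse 1119, 1192 or 1199 and 1 without the pairing. The gastric mucin gene Muc5ac had 3 counts over the surrounding libraries and 3 over the polyps and was below the filter (adjusted p = 0.978 with no filter). Tested gastric-type and serrated lesion genes numbered 4, too few for a list test, and 0 of them passed (adjusted over the list alone, 1 rose, Vsig1, and 1 fell, Hepacam2). With DESeq2 1 rose, and with no filter or a mean of at least 5 CPM 1 rose and 1 fell. Vsig1 was at 2.17 ± 0.53, Hepacam2 at -1.20 ± 0.29, Msln at 1.08 ± 0.62 and Ctse at -2.10 ± 2.12.

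In the interferon response list 0 of 19 tested genes rose and 2 fell (0 and 3 adjusted over the list alone). For interferon response genes, camera gave adjusted p = 8.76e-06, and adjusted p = 0.325 with an estimated correlation. Log2 fold changes were negative for 18 of 19 genes, with a median of -0.65 (-1.51 without mouse 1119 and -0.42 without mouse 1192). Ido1 went from 14.8 ± 13.7 to 2.55 ± 1.298 CPM and Gbp2, a guanylate-binding protein gene, from 32.97 ± 35.5 to 8.68 ± 4.95 CPM (adjusted p = 0.0213 and 0.0474). The antigen-processing genes Tap1 and Psmb8 did not pass (adjusted p = 0.0712 and 0.231). Interferon response genes that passed numbered 1, 2 and 0 without mouse 1119, 1192 or 1199 and 0 without the pairing, and the list kept its call in each case. In the dendritic cell and MHC class II list, 0 of 7 fell (1 adjusted over the list alone), at a median of -1.38 (-2.25 without mouse 1119 and -0.56 without mouse 1199). For dendritic cell and MHC class II genes, camera gave adjusted p = 0.03097, and adjusted p = 0.491 with an estimated correlation. Its call ended without mouse 1192, without mouse 1199 or with no filter (adjusted p = 0.609, 0.615 and 0.06200). The T cell and innate lymphoid list had 5 tested genes, of which 0 fell (0 adjusted over the list alone), at a median of -1.58 (-0.98 without mouse 1192 and -0.79 with limma-voom). For T cell and innate lymphoid genes, camera gave adjusted p = 0.03097, and adjusted p = 0.351 with an estimated correlation. It also lost its call without mouse 1192 or 1199 (adjusted p = 0.0564 and 0.0728), and without mouse 1119 it had too few genes for the test. Among inflammatory cytokines and chemokines 10 of 11 log2 fold changes were positive, with a median of 2.22, but 0 passed singly, also 0 adjusted over the list alone. For inflammatory cytokine and chemokine genes, camera gave adjusted p = 0.00255, and adjusted p = 0.351 with an estimated correlation. Its median was 0.91 without the pairing, 0.92 with limma-voom and 1.32 without mouse 1192, and its call ended at a mean of at least 5 CPM (adjusted p = 0.0525). Il1b, at 2.53 ± 2.15 and 9.76 ± 8.11 CPM, did not pass (log2 fold change 2.22 ± 0.77, adjusted p = 0.223). In the macrophage and monocyte list 1 of 11 tested genes rose and 0 fell (3 and 0 adjusted over the list alone). For macrophage and monocyte genes, camera gave adjusted p = 0.0106, and adjusted p = 0.351 with an estimated correlation. The gene that rose was Arg1, from 5.69 ± 4.87 to 35.9 ± 19.3 CPM. Cd14, Lyz2 and Adgre1 were at 0.81 ± 0.24, 0.94 ± 0.29 and 2.03 ± 1.58. Arg1 did not pass without mouse 1119 or without the pairing, and the list lost its call without mouse 1119 (adjusted p = 0.0743). Neutrophil genes were too few to test as a list, with Mmp9 at 1.89 ± 0.44 (adjusted p = 0.06704), and with no filter the list passed camera (adjusted p = 0.00269). S100a8 had 10 counts over the surrounding libraries and 64 over the polyps, 56 of them in mouse 1119 (adjusted p = 0.815 with no filter).

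In the growth arrest and senescence list 4 of 12 tested genes rose and 0 fell (5 and 0 adjusted over the list alone). For growth arrest and senescence genes, camera gave adjusted p = 2.54e-04, and adjusted p = 0.351 with an estimated correlation. Members that rose included 3 insulin-like growth factor binding protein genes. Igfbp5 went from 28.6 ± 18.2 to 102 ± 65.7 CPM, and Igfbp3 and Igfbp7 had log2 fold changes of 1.93 ± 0.40 and 1.54 ± 0.33. These 3 genes code for secreted proteins that stromal cells also make. Growth arrest and senescence genes that passed numbered 1, 3 and 1 without mouse 1119, 1192 or 1199 and 1 without the pairing. Cdkn2a had 0 counts in all 6 libraries. There 3 counts would be 0.225 to 0.452 CPM over raw library totals, without the normalization of the other CPM values. Of 28 cell cycle genes 0 passed, also 0 adjusted over the list alone, at a median of -0.47 (camera adjusted p = 0.07303). Without mouse 1192 the median was -0.25 (adjusted p = 0.353). The cell cycle list passed without mouse 1119 (adjusted p = 0.00201), without the pairing (0.0471) and with no filter (0.0371). Mki67 was at 40.6 ± 20.96 CPM in surrounding tissue and 29.00 ± 8.28 in polyps (adjusted p = 0.557). The stem cell gene Lgr5 had 25 counts over the surrounding libraries and 3 over the polyps and was below the filter (adjusted p = 0.914 with no filter). In the Wnt target and stem cell list 0 of 10 genes passed (1 adjusted over the list alone). Ephb2 had the smallest p (log2 fold change 0.77 ± 0.18, adjusted p = 0.0675), and the list did not stand apart from other genes (camera adjusted p = 0.988).

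Of 44 lists fixed before the data were examined, 38 had at least 5 tested genes, and 23 of these passed camera at its preset correlation of 0.01 (14 up and 9 down). When the correlation was estimated from the data, 0 lists passed camera, and the adjusted p of these 23 lay between 0.205 and 0.491. That setting tests on the 2 residual degrees of freedom of this design and so has little power. The adipocyte and mesothelial list was among the 23, although its called members went apart, Krt19 rising by 0.73 ± 0.15 and Pck1, the gluconeogenic enzyme gene, falling by 1.88 on the log2 scale, and 0 members passed with any 1 mouse left out or without the pairing. For adipocyte and mesothelial genes, camera gave adjusted p = 0.0234, and adjusted p = 0.314 with an estimated correlation. Krt19 is also a keratin of the intestinal epithelium, and the list lost its call without mouse 1119, without mouse 1192 or at a mean of at least 5 CPM (adjusted p = 0.131, 0.0846 and 0.06605). Lists that did not pass included oxidative phosphorylation (adjusted p = 0.288), the unfolded protein response (0.4699), Notch (0.0878), antimicrobial defence (0.148), and B and plasma cells (0.542). Nor did tuft cells (adjusted p = 0.124), enteroendocrine cells (0.988) or sterol and lipid synthesis (0.288), in which the desaturase gene Scd1 fell by 1.60 on the log2 scale but did not pass without mouse 1119, without mouse 1199 or without the pairing. Antimicrobial defence passed without mouse 1119 or without the pairing (adjusted p = 2.42e-09 and 0.0471), B and plasma cells with no filter (adjusted p = 0.00269) and oxidative phosphorylation without mouse 1192 (adjusted p = 0.0197). Besides the immediate early genes, which passed (adjusted p = 1.42e-08), lists that track tissue and RNA handling did not pass, with adjusted p = 0.0623 for mitochondrially encoded genes and 0.855 for ribosomal protein genes. The adjusted p was 0.721 for histone genes and 0.613 for structural RNAs without a poly(A) tail. Mitochondrially encoded genes passed without mouse 1119 or 1192 (adjusted p = 7.07e-04 and 0.03104), with upper-quartile normalization (0.0463) and with no filter (0.0129), and ribosomal protein genes without mouse 1199 (adjusted p = 0.0324). Mast cell and eosinophil genes and blood genes had 2 and 4 tested members, of which 0 passed, with the hemoglobin gene Hbb-bs at 1.43 ± 0.58.

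**Figure D3:**
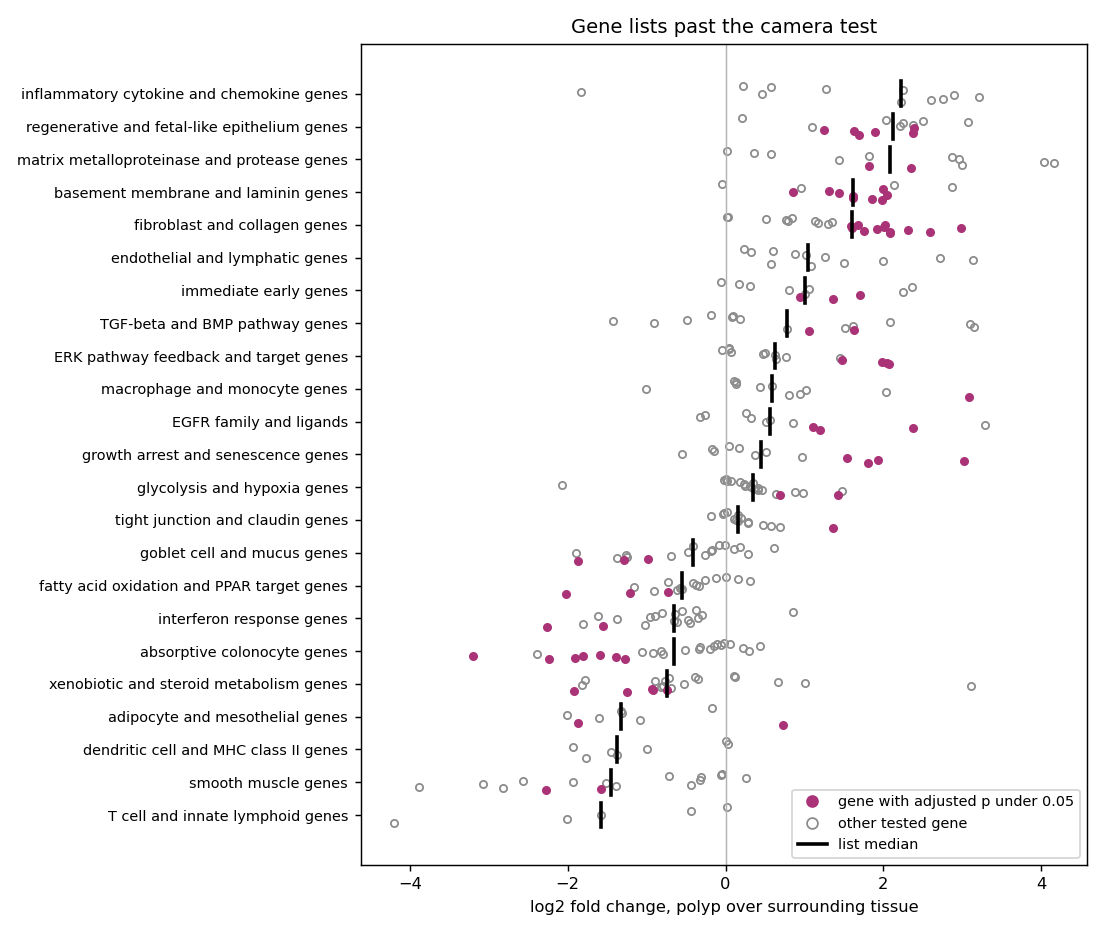
Log2 fold change of polyp over surrounding tissue for each tested gene of the 23 lists past camera at the preset correlation; filled points are genes with an adjusted p under 0.05 over all 10960 genes, open points other tested genes and black bars list medians. Called members numbered 12 in the fibroblast and collagen list and 0 in the inflammatory cytokine and chemokine list.

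Across libraries, Pearson correlations of log2 CPM over genes ranged from 0.841, between both samples of mouse 1192, to 0.937, between the polyps of mice 1119 and 1199. The first principal component held 37.8% of the variance and 47.2% of that component lay between tissues. The polyp of mouse 1192 stood apart on it, with a score of 87.9 against -2.704 and 0.235 for the other polyps and -37.7 to -20.8 for surrounding tissue. The second held 28.6%, of which 36.2% lay between tissues and 59.4% between mice.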

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

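The trend removal was chosen after seeing the data, and the other alternatives before. The 303 genes kept their sign in the 11 alternatives that tested all of them. So did the 298 tested with a mean of at least 5 CPM and the 301 with the trend removed. These fits reuse libraries of the main fit, so agreement in sign was favoured in advance. Between 254 and 313 genes were called with RLE or upper-quartile normalization, without large genes, without robust spread estimates or with the trend removed, with 247 to 302 of the 303 kept, and 411 with limma-voom. Counts moved further with no filter (753, of which 442 higher and 311 lower, over 21370 genes), a mean of at least 5 CPM (445, of which 267 higher and 178 lower), and DESeq2 (501, of which 305 higher and 196 lower; adjusted p given as NA stayed NA and out of the counts); their cause was not tested. Against a log2 fold change of 1, 3 genes passed, which the stricter hypothesis requires to be no more than 303. Leaving out a mouse, which removes a pair and leaves fewer samples, gave 83 to 281 genes, 45 to 153 higher and 21 to 128 lower, and kept 71, 198 and 84 of the 303 without mouse 1119, 1192 and 1199. The paired design mattered: without the replicate block 87 genes passed, 51 higher and 36 lower, each of them among the 303, and of the called lists none lost its call.

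Between 17 and 26 lists passed camera across the alternative fits, against 23, but 0 with an estimated correlation and 1 with fry, whose cause was not tested. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 303 genes and the highest other split 1. Of the 4 splits that part all pairs the other 3 gave 0. In the other splits part of the difference between polyp and surrounding tissue stays in the residual spread and lowers the calls. Their counts therefore do not show what libraries without a tissue difference would give. Muc5ac, Lgr5 and S100a8 were below the filter and did not pass with no filter, and Cdkn2a had 0 counts. At these depths simulated 2-fold changes were recovered in 26.6% of cases.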

Other observations

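Other groups of genes with a shared name stem were compared over all tested genes, 189 stems with at least 8 tested members and both directions (378 Fisher's exact tests, two-sided, Benjamini-Hochberg adjusted). Collagen genes were the only stem that passed, with 11 of 21 higher in polyps and 0 lower (adjusted p = 3.44e-12), in a test that treats genes as independent. The fibroblast and collagen list, which shares many of them, had adjusted p = 0.205 with an estimated correlation. Besides those of the fixed lists the collagen genes included Col18a1 and Col6a4. TNF receptor family genes (3 of 9 higher, Tnfrsf11b, Tnfrsf12a and Tnfrsf23), annexins (3 of 10, Anxa2, Anxa3 and Anxa5), the stem of S and a digit, most of it S100 genes (3 of 11, S100a11, S100a14 and S100a16) and dual-specificity phosphatases (3 of 12, Dusp1, Dusp4 and Dusp5) did not pass, with adjusted p between 0.0698 and 0.0748. Anxa2 went from 273 ± 108 to 599.5 ± 68.4 CPM and Anxa5 from 23.1 ± 18.7 to 97.9 ± 11.2 CPM. Carboxylesterase genes had 2 of 9 lower, Ces1g and Ces2c (adjusted p = 0.232). These genes were named after their values were seen.

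Among single genes outside the naming rule and noticed in the same way, integrin genes Itga2, Itga6, Itgav and Itgb8 had log2 fold changes of 1.69 ± 0.22, 1.21 ± 0.16, 1.04 ± 0.18 and 2.06 ± 0.43 (as name stems, 2 of 8 Itga and 1 of 9 Itgb genes were higher, adjusted p = 0.365 and 1), and the keratin genes Krt18 and Krt8 1.57 ± 0.19 and 0.71 ± 0.15, all past the threshold. The complement regulator gene Cd55 went from 30.2 ± 15.5 to 101 ± 26.1 CPM (adjusted p = 0.0116). The homeobox gene Hoxa10, from 13.8 ± 2.095 to 3.98 ± 1.42 CPM (adjusted p = 0.0244), and the transcription factor gene Klf4, from 282 ± 36.3 to 151 ± 42.5 CPM (adjusted p = 0.0174), fell. Labels place the surrounding tissue in the distal cecum and give no position for the polyps. Lars2, which held 0.0347% to 1.14% of the counts outside the mitochondrial rRNAs, did not pass (log2 fold change 1.24 ± 0.77, adjusted p = 0.584), and whether rRNA reads count toward it was not tested.

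Of the tests below, the one on genes that all cells use was chosen before its result was seen and the others after; the bound for the general epithelial genes was reset after a first one, a median above 0 in each mouse, had not been met, and the smooth muscle test replaced one on Myh11, Actg2, Des and Tagln, all lower in each mouse. Of the colonocyte list 7 of 24 tested genes fell (median log2 fold change -0.65), while 12 of 22 fibroblast and collagen genes rose. For each of these lists camera gave adjusted p = 0.205 with an estimated correlation. A smaller share of epithelium in the polyp samples would lower all epithelial genes. The 25 general epithelial genes, 12 of them positive, had a median of -0.043 (quartiles -0.18 and 0.29) and ran from Cdx1 at -0.59 to Cdh1 at 0.64. By mouse, the median was -0.133, 0.0244 and 0.00888 in mice 1119, 1192 and 1199. These values argue against a smaller share of epithelium as the whole cause. A change in the state of the epithelium stays open as a hypothesis, as does the position within the cecum.

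The rise of collagen, laminin and nidogen genes was set against transcript length and GC content and against tissue composition. Whether the removal of mammalian RNA before sequencing played a part was not tested. With the trend of each library with transcript length and GC content removed, the fibroblast and collagen median was 1.64 and the basement membrane median 1.64, against 1.60 and 1.62 before, which argues against that bias. A larger share of all stromal cells, smooth muscle included, would raise smooth muscle genes too, but their median was -1.45. Lower expression per cell could also give that median, and it does not bear on stroma other than muscle. A larger share of fibroblasts and endothelium, or more matrix transcript per cell, may account for the rise, and these data do not separate them. Of the smooth muscle genes 10 of 16 were lower in all 3 mice, short of the 12 set as the bound. That count cannot separate a smaller share of muscle in the polyp samples from lower expression per cell, since either would lower these genes.

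The polyp library of mouse 1192 had the fewest detected genes. Depth is argued against, because at equal thinned counts it still had 12326 genes against 14295 or more in the others. Few distinct molecules in that library may account for it: of genes that all cells use with a mean of 5 to 20 thinned counts in the other 5 libraries, 15.6% of 64 had 0 counts there, against 0% to 1.67% in the other libraries measured in the same way. Over all genes of that abundance the shares were 22.96% and 3.698% to 9.14%. Without this mouse 281 genes were called, 198 of the 303 among them.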
